A study of Mus musculus with 24 samples.

How the data were processed

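Bone marrow cells of C57BL/6 mice were grown into eosinophils and their polyadenylated RNA was sequenced from strand-specific libraries, per the labels' protocols. The cells received stem cell factor and FLT3 ligand at 100 ng/ml each from day 0 to day 4 and interleukin-5 (IL-5) at 10 ng/ml from then on. On day 13 dead cells were removed, and the remaining cells were kept overnight in IL-5 alone or with granulocyte-macrophage colony-stimulating factor (GM-CSF) at 20 ng/ml. The labels also give interleukin-10 (IL-10) arms, whose dose they do not state. Of the 24 libraries, 12 came from wild-type cells, 6 from cells labelled Csf2ra-/- and 6 from cells labelled Irf5-/-. They made 8 groups of 3 libraries. The wild-type groups were untreated, GM-CSF, IL-10 and both cytokines, and each knockout had an untreated and a GM-CSF group. Replicate numbers were given in the order of the deposit and only name the libraries. The labels pair none across groups, so no block was fitted and libraries were treated as independent. In the libraries labelled Irf5-/- the sum of 4 Y-linked genes was 179, 12.2 and 39.2 CPM untreated and 165, 13.4 and 44.2 CPM with GM-CSF, in the order of the numbers, so cultures shared between treatments are not excluded. In wild type the first library of each group by title number had 184 (GM-CSF), 186 (both cytokines), 175 (IL-10) and 175 CPM (untreated). Each group also held a library at 45.8 to 59.9 CPM. The last libraries by title number did not match, at 52.6, 174, 54.3 and 50.7 CPM. Shared cultures are thus not excluded there either, also between comparisons that share no library. The labels speak of triplicate stimulations and do not say whether replicates came from separate animals or cultures. The p-values therefore measure only the spread between these libraries. In Csf2ra-/- it may be technical, while within each wild-type group and each group labelled Irf5-/- the Y-linked sums lay too far apart for all 3 libraries to be repeats of 1 culture. They leave open that 2 of the 3 were, as with 59.9 and 54.3 CPM in wild-type IL-10 replicates 1 and 2.

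The deposited files hold 1 read count per Ensembl gene and library, per the file headers. Reads were aligned with STAR and counted per gene with featureCounts on GRCm38.p6, per the submitters' processing notes, which give no versions. All values checked were whole counts of 0 or more, with no sign of a prior scaling. The strand setting and the handling of reads that match several genes are not given in the sources used here, so values of near-identical or overlapping genes such as Bcl2a1d, Bcl2a1b, Ugt1a8, Csf2rb and Csf2rb2 are uncertain. Symbols and coordinates came from GENCODE mouse release 21 on GRCm38. Each file listed 25746 genes, of which 111 had no symbol and held 0.039% of the counts.

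Total counts per library ranged from 6222979 to 18709153. Counts were scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 on R 4.3.3, with factors between 0.939 and 1.031. edgeR's filterByExpr kept 11885 genes, and Cxcl9 and Cxcl10 were among those it removed. Levels are given as TMM-scaled CPM, mean and SD over 3 libraries. The sums of 4 Y-linked genes are the exception and are given per library as CPM of the total counts, without TMM scaling. The covariate made from these genes used their TMM-scaled level. One model of 8 group means was fitted to all 24 libraries with edgeR's robust quasi-likelihood method, and the common biological coefficient of variation was 14.1%. The 12 comparisons were contrasts of this model. They were the GM-CSF effect in each genotype and in IL-10-treated wild-type cells, the IL-10 effect with and without GM-CSF, each knockout against wild type, and 3 differences between effects. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 over all tested genes. All adjusted p-values for genes come from edgeR's quasi-likelihood F-test with BH adjustment unless another tool is named. Log2 fold changes are given ± SE. A ratio against a group with 1 to 3 counts is given with its exact 95% counting interval, which covers counting error only.

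Gene lists numbering 34 were tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, two-sided, BH-adjusted over the lists within a comparison. Camera with an estimated correlation stands beside it, and 25 of the 118 list calls of the 12 comparisons held with it. For each list the members called over all genes and the members called when adjusted over the list alone were counted. The comparisons, tests, gene lists and rule for named genes were set before the data were examined. By that rule a named gene had an adjusted p under 0.05, replicates that did not overlap between the groups compared (a 10% chance for 3 against 3, not asked for differences of effects), a mean of at least 5 CPM and a symbol that is not a predicted model. The 10 largest rises and 10 largest falls were taken in the GM-CSF effect in wild type and in both IL-10 effects, 5 and 5 in the other comparisons and 4 and 4 in the differences. The targeted genes, 5 cytokine receptors, 16 genes of prior interest and up to 4 members per list with the smallest adjusted p were added. A named gene or list called under neither of the settings compared counted as unchanged whatever its sign.

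The scripts were tested on counts simulated from the real means and library sizes with a seeded set of changed genes. For the GM-CSF effect in wild type, with 11755 simulated genes tested, edgeR recovered 43.3% of changes of 1.5-fold, 81.8% of 2-fold and 93.9% of 4-fold, with 6 unchanged genes called. For the difference of the GM-CSF effect between Csf2ra-/- and wild type, it recovered 14.9%, 62.1% and 89.4%, with 7 unchanged genes called. The simulated genes varied independently, with the same spread in every group. The real untreated Csf2ra-/- libraries differed more among themselves than the untreated wild-type ones. Their chi-square per degree of freedom between pairs of replicates was 34.85 to 66.26 against 7.08 to 16.3. These figures may therefore be too favourable for this difference.

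The alternatives tried were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a stricter one (1 CPM and 10 counts in at least 3 libraries), a fit of the compared groups only, no fold minimum for the overlaps, an estimated correlation for the lists, and each library left out in turn. Where that left 2 libraries in a group, the pooled fit assumes that they vary like the other groups. Another 4 settings were added after seeing the data. They were the level of 4 Y-linked genes as a covariate, the score on the leading axis of variation within groups as a covariate, the deviation from the group mean along that axis as a covariate, and the joint removal of 3 libraries. Those 3 were untreated Csf2ra-/- replicate 1 and untreated replicate 1 of the libraries labelled Irf5-/-, which had the fewest counts, and wild-type GM-CSF with IL-10 replicate 3, which had the most genes with a count. Both axis covariates were made from the deviations of these same libraries from their group means. Fitting them therefore takes up part of the spread that the tests measure against. The deviation is centred in each group, so it can hardly move a group difference. The score differs from it only by a constant per group, so it can shift group differences. Higher counts of calls with either are thus no check of robustness. For every comparison the labels of the libraries were also regrouped. This was done in all 10 ways for 3 against 3 and in 100 drawn ways for the differences.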

Results

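RNA was sequenced from 24 libraries of mouse eosinophils grown from bone marrow, in 8 groups of 3. Wild-type cells were left untreated or kept overnight with GM-CSF, with IL-10 or with both, and cells labelled Csf2ra-/- or Irf5-/- were left untreated or given GM-CSF. Csf2ra encodes the ligand-binding chain of the GM-CSF receptor and Irf5 a transcription factor of innate immune cells. Total counts ranged from 6222979 in untreated replicate 1 of the libraries labelled Irf5-/- to 18709153 in wild-type GM-CSF with IL-10 replicate 3. Between 12910 and 15196 genes had a count. The eosinophil granule genes Prg2 (major basic protein) and Epx (eosinophil peroxidase) were high in all groups, at 42939 ± 2623 CPM and 14937 ± 1090.3 CPM in untreated wild-type cells (SD, n = 3). The 10 most abundant genes took 10.52% to 13.79% of the counts, and mitochondrial transcripts 0.62% to 0.95%.

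The targeted genes were read first, since they check the labels. Irf5 (ENSMUSG00000029771, GRCm38 chromosome 6, 29526625 to 29541871) stood at 1394 to 1999 CPM in the 6 libraries labelled Irf5-/-, with a mean of 1669 CPM. In the other 18 libraries it stood at 28.3 to 94.3 CPM, with a mean of 53.0 CPM. The targeted gene thus went against its label, with counts 31.5 times the mean of the other libraries, and each direction drawn from these 6 libraries below rests on a label that the gene-level count does not bear out. Csf2ra (ENSMUSG00000059326, chromosome 19, 61223957 to 61228429) stood at 28.5 to 39.8 CPM in the 6 libraries labelled Csf2ra-/- (mean 35.5 CPM) and at 41.8 to 83.8 CPM in the other 18 (mean 62.9 CPM). Its counts were lower by a ratio of 0.564 and not absent. In untreated cells the log2 fold change of Csf2ra against wild type was -0.80 ± 0.14 (adjusted p = 0.00171). Counts per gene do not show which exons the reads came from, so they do not tell whether a functional transcript was made.

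**Figure D1:**
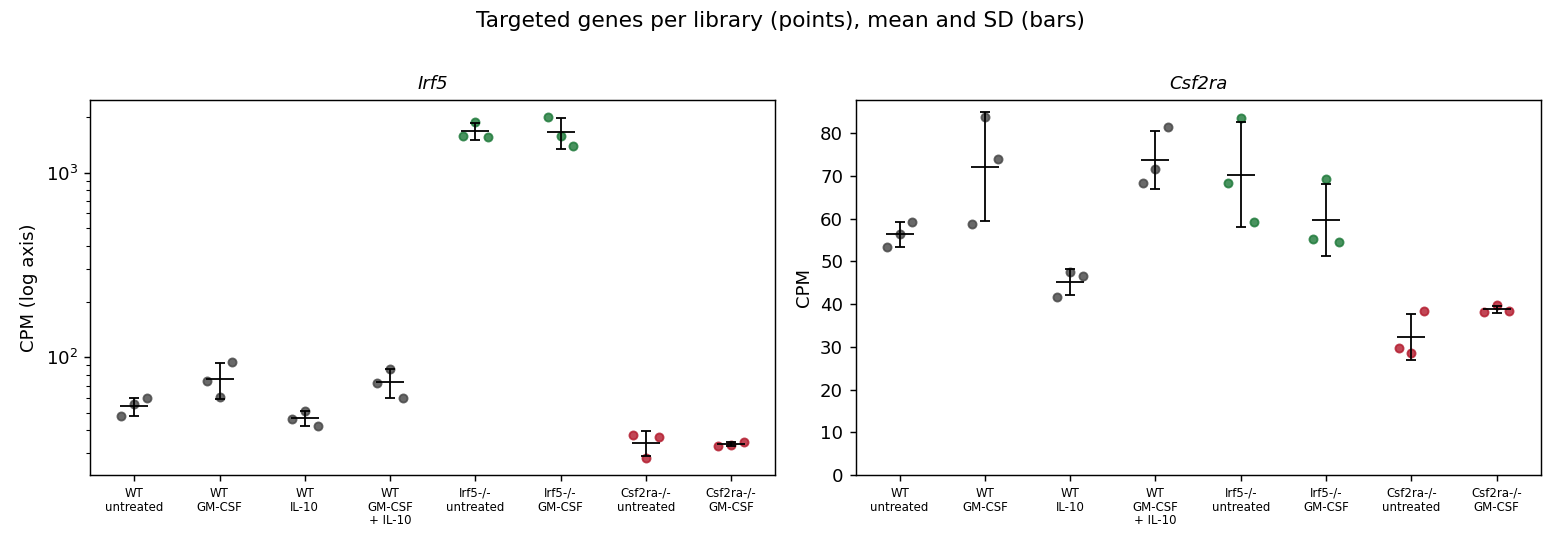
TMM-scaled CPM of Irf5 (log axis) and Csf2ra (linear axis) in the 8 groups, with 1 point per library and the mean and SD of 3 libraries as bars. Irf5 lies between 1394 and 1999 CPM in the libraries labelled Irf5-/- and at or below 94.3 CPM elsewhere, and Csf2ra lies at or below 39.8 CPM in the libraries labelled Csf2ra-/-.

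The first comparison asked how wild-type eosinophils respond to GM-CSF. GM-CSF raised a set of chemokine genes and some single receptor genes. Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), a chemokine for CCR4-bearing lymphocytes, went from 4.43 ± 0.77 to 136 ± 49.6 CPM (SD, n = 3; log2 fold change 4.93 ± 0.42, adjusted p = 1.49e-06). Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683), another chemokine gene, rose from 6.49 ± 2.15 to 46.5 ± 8.21 CPM (2.83 ± 0.26, adjusted p = 1.49e-06). Clec4n (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021), a fungal pattern receptor, rose from 5.02 ± 2.38 to 37.9 ± 5.56 CPM (2.89 ± 0.28, adjusted p = 4.43e-06). The eotaxin Ccl24 and the CCR4 ligand Ccl22 rose by log2 fold changes of 2.94 ± 0.46 and 2.16 ± 0.35. Plet1, a surface protein of progenitor and dendritic cells, had 2116 counts over the 3 GM-CSF libraries and 1 count over the 3 untreated ones, a ratio of 1720 with a 95% counting interval of 308 to 67986. Among the falls, Igf1, a growth factor, went from 19.0 ± 1.64 to 3.42 ± 1.75 CPM (-2.49 ± 0.34, adjusted p = 0.000464). The immediate early transcription factor Egr1 went from 329 ± 73.7 to 98.2 ± 27.1 CPM (-1.74 ± 0.22, adjusted p = 0.000177). The sugar phosphate transporter Slc37a2 (-1.86 ± 0.29) and the receptor Cd300ld (-0.86 ± 0.14) fell too.

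In all, edgeR called 49 genes higher and 17 lower with GM-CSF in wild type, of which 38 and 15 by at least 2-fold, and the log2 fold change of all tested genes had a median of -0.01. The count fell to 31 without untreated replicate 2, to 35 without untreated replicate 3 and to 35 without GM-CSF replicate 1. Il1b, which encodes interleukin-1 beta, was called at 1.87 ± 0.33 (adjusted p = 0.00403) and lost its call without untreated replicate 2 (adjusted p = 0.054) or 3 (adjusted p = 0.055). DESeq2 called 112 genes and limma-voom 216, among them 66 and 65 of the 66. The sum of 4 Y-linked genes differed between the libraries compared, at 175, 56.9 and 50.7 CPM untreated and 184, 176 and 52.6 CPM with GM-CSF, and with its level as a covariate 63 genes were called.

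By group, 13 lists were called, 6 of them also with an estimated correlation, and chemokines had the smallest adjusted p. Of 13 measured chemokine genes 6 rose with GM-CSF (8 adjusted over the list alone), among them Ccl17, Ccl4, Ccl24 and the neutrophil attractant Cxcl2 (1.17 ± 0.18), and the list as a whole was higher (camera adjusted p = 8.3e-32, and adjusted p = 0.00026 with an estimated correlation). Of 15 costimulatory and checkpoint ligands 1 rose, Tnfsf4 (OX40 ligand, 2.35 ± 0.36), against 5 adjusted over the list alone, and the list was higher (adjusted p = 6.24e-06, and 0.0014 with an estimated correlation). Cd274, which encodes PD-L1, stood at 36.5 ± 3.32 CPM against 28.3 ± 2.37 CPM (0.37 ± 0.16, adjusted p = 0.681), and Cd80 at 0.45 ± 0.13 on the log2 scale (adjusted p = 0.224). Of 5 type 2 and regulatory cytokines 1 rose, Il13 (1.53 ± 0.22; 2 adjusted over the list alone; list adjusted p = 2.44e-05, and 0.043 with an estimated correlation). Among 23 targets and feedback genes of NF-kB and 23 apoptosis regulators, 2 rose in each, the survival factors Bcl2a1d (2.54 ± 0.37) and Bcl2a1b, with 5 and 4 adjusted over the list alone. Bcl2a1b (0.64 ± 0.14) lost its call with any 1 of the 6 libraries left out (adjusted p of 0.065 to 0.26), and the lists' adjusted p-values were 0.000137 and 0.00026 (0.0096 and 0.021 with an estimated correlation).

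Monocyte and macrophage markers were lower with GM-CSF as a list (18 genes, median log2 fold change -0.55, adjusted p = 1.64e-07, and 0.047 with an estimated correlation). Only 1 of the 18 passed over all genes, Cx3cr1, and 4 adjusted over the list alone. Cx3cr1 lost its call without any library but untreated replicate 3 (adjusted p of 0.096 to 0.19). The level of the macrophage receptor Mrc1 differed widely among the GM-CSF libraries, at 6.17, 1.86 and 17.2 CPM. Inflammatory cytokines (3 of 12 called over all genes and adjusted over the list alone, Il1b, Il1a and Tnf; adjusted p = 0.00741) were higher with the preset correlation and not with an estimated one (adjusted p = 0.075). The same held for STAT5 targets (1 of 18, the cyclin gene Ccnd2 at 0.70 ± 0.11; 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000724, and 0.22 with an estimated correlation). The inflammatory list had an adjusted p of 0.0982 without untreated replicate 1 and 0.128 without GM-CSF replicate 2, with limma-voom of 0.244 and with no low-count filter of 0.457, and the STAT5 list 0.0869 without untreated replicate 1 and 0.054 without GM-CSF replicate 3. Tnf and Il1a lost their calls without any library but GM-CSF replicate 3 (adjusted p of 0.052 to 0.24). Ribosome biogenesis genes had 0 of 24 called by edgeR under either adjustment and a median of 0.35. Their adjusted p of 2.65e-10 was 0.14 with an estimated correlation. Outside these, the bacterial lipoprotein receptor Tlr2 (1.24 ± 0.19), the matrix protein Spp1 (1.31 ± 0.19), the growth factor Hbegf (1.19 ± 0.21) and the integrin Itgax (0.70 ± 0.11) rose. Of 24 pattern-recognition and Fc receptors 2 rose, Clec4n and Tlr2 (4 higher and 2 lower adjusted over the list alone), and the list was not called (adjusted p = 0.118, and 0.38 with an estimated correlation). Of 25 eosinophil granule and lineage genes edgeR called 0, with Epx at -0.08 ± 0.10, Prg2 at -0.05 ± 0.12 and Siglecf at 0.01 ± 0.18. None of the receptor genes Csf2ra, Csf2rb, Csf2rb2, Il5ra, Il10ra and Il10rb passed the test.

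**Figure D2:**
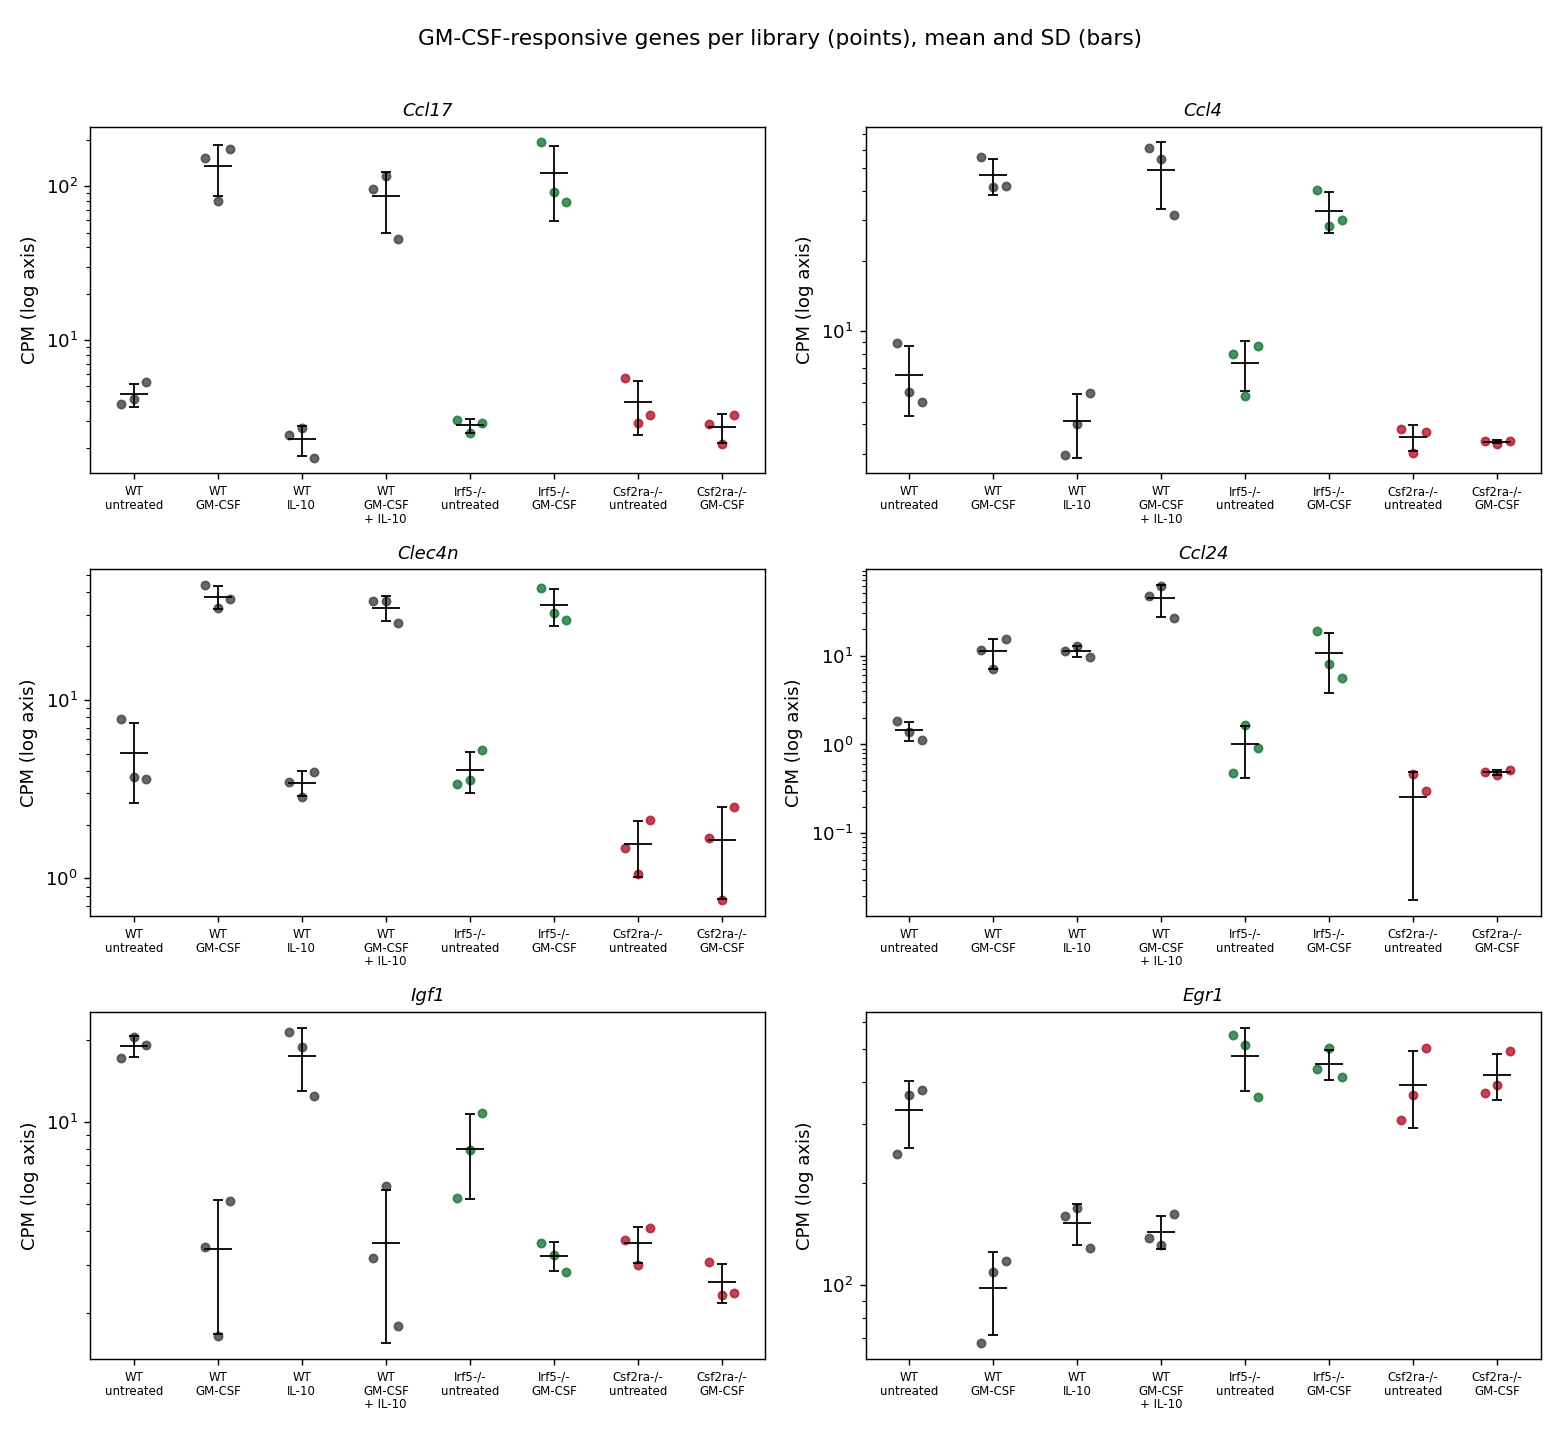
TMM-scaled CPM of Ccl17, Ccl4, Clec4n, Ccl24, Igf1 and Egr1 (log axes) in the 8 groups, with 1 point per library and the mean and SD of 3 libraries as bars; a Ccl24 count of 0 in 1 untreated Csf2ra-/- library is not drawn. Ccl17 rises from 4.43 to 136 CPM with GM-CSF in wild type and stays at 3.94 and 2.74 CPM in Csf2ra-/-, and Egr1 is at 98.2 CPM in wild type with GM-CSF and at 451 CPM in the libraries labelled Irf5-/- with GM-CSF.

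The IL-10 comparison without GM-CSF asked what IL-10 alone changes. IL-10 raised 6 genes and lowered 0. Bcl3, an NF-kB regulator and known STAT3 target, rose from 7.45 ± 1.98 to 25.8 ± 1.99 CPM (SD, n = 3; log2 fold change 1.80 ± 0.26, adjusted p = 0.00785). Ccl24 rose from 1.44 ± 0.36 to 11.3 ± 1.64 CPM (2.95 ± 0.46, adjusted p = 0.0135), and the inflammatory caspase gene Casp4 from 2.95 ± 0.55 to 6.28 ± 0.91 CPM (1.09 ± 0.18, adjusted p = 0.017). The others were Gpr15, Arid5a and Cd244a at 0.83, 0.76 and 0.65. The levels of Il10ra did not pass (-0.05 ± 0.24), nor did Socs3 (0.64 ± 0.21, adjusted p = 0.704) or Tnf (-0.59 ± 0.12, adjusted p = 0.0684). In the list of 19 IL-10 and STAT3 targets only Bcl3 passed, with 5 higher and 1 lower adjusted over the list alone (list adjusted p = 0.00616, and 0.63 with an estimated correlation). That list had an adjusted p of 0.394 without untreated replicate 1 and 0.0618 without IL-10 replicate 2. The inflammatory cytokines had a mean of -0.30 over 12 genes, 0 called over all genes and 1 lower, Tnf, adjusted over the list alone (adjusted p = 0.00243, and 0.066 with an estimated correlation). Among markers of other cell types, the 18 monocyte and macrophage markers had a mean of 0.38 and 0 members called by edgeR under either adjustment (adjusted p = 0.0324, and 0.697 with an estimated correlation), with Mrc1 at 91.9, 71.8 and 36.3 CPM with IL-10 and 15.7, 22.6 and 23.1 CPM untreated. The list had an adjusted p of 0.166, 0.0755 and 0.0922 without untreated replicate 1, 2 or 3, of 0.251 without IL-10 replicate 1 and of 0.133 with a stricter low-count filter. The 17 neutrophil markers had a mean of 0.12, 0 called by edgeR over all genes and 2 higher adjusted over the list alone (adjusted p = 0.0207, and 0.633 with an estimated correlation). Their adjusted p was 0.357 without untreated replicate 2, 0.549 without IL-10 replicate 3, 0.108 with limma-voom and 0.0916 with no low-count filter. Of the 8 lists called here 0 held with an estimated correlation. At an unadjusted p under 0.05 stood 539 genes, DESeq2 called 30 genes and limma-voom 138, each including the 6. Gpr15 and Cd244a lost their calls with any 1 of the 6 libraries left out (adjusted p of 0.0898 to 0.256 and 0.0569 to 0.245). The other calls rested on single libraries as well, since 0 genes were called without untreated replicate 3 or without IL-10 replicate 1, 1 without untreated replicate 2 and 2 without IL-10 replicate 2. Bcl3 had an adjusted p of 0.089 and 0.056 in the first 2 of these fits, Ccl24 of 0.21 and 0.056, Arid5a of 0.21 and 0.0557, and Casp4 of 0.25 and 0.093. Without untreated replicate 2 the adjusted p was 0.11 for Ccl24 and Casp4 and 0.133 for Arid5a, without IL-10 replicate 2 it was 0.068 for Ccl24 and 0.14 for Casp4, and without IL-10 replicate 3 it was 0.0577 for Arid5a.

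The IL-10 comparison with GM-CSF asked whether IL-10 changes GM-CSF-treated cells. IL-10 again raised 6 genes and lowered 0 by edgeR. At an unadjusted p under 0.05 stood 382 genes, DESeq2 called 20 higher and 1 lower, and limma-voom called 19. With only the groups compared in the fit edgeR called 0 genes, and with the Y-linked level as a covariate it called 3. Bcl3 went from 8.32 ± 1.10 to 29.8 ± 9.61 CPM (1.84 ± 0.26, adjusted p = 0.00391) and Ccl24 from 11.3 ± 4.14 to 44.5 ± 17.3 CPM (1.98 ± 0.36, adjusted p = 0.045). The kinase gene Jak3 went from 45.3 ± 11.7 to 131 ± 35.8 CPM (1.53 ± 0.26, adjusted p = 0.0317). The fatty acid receptor gene Ffar2 went from 167 ± 20.4 to 269 ± 24.8 CPM (0.69 ± 0.12, adjusted p = 0.0317), and the secreted glycoprotein Lrg1 from 4.67 ± 0.65 to 12.3 ± 0.87 CPM (1.40 ± 0.26, adjusted p = 0.045). The RNA-binding protein gene Igf2bp2 was another (1.46 ± 0.27, adjusted p = 0.045) and was chosen after its values were seen. Bcl3 and Ccl24 were called in both IL-10 comparisons, 2 genes against 0.00303 for independent lists, and all 6 genes of each comparison had the same sign in the other. Cd274 was at 0.20 ± 0.16 (adjusted p = 1). Without GM-CSF replicate 1 the count was 0, without GM-CSF with IL-10 replicate 2 it was 1, and without GM-CSF replicate 2 or 3 it was 2. Bcl3 lost its call only without GM-CSF replicate 1 (adjusted p = 0.079), where Ccl24, Jak3, Lrg1 and Ffar2 all stood at an adjusted p of 0.27 and Igf2bp2 at 0.0787. Without GM-CSF with IL-10 replicate 2 the adjusted p was 0.2 for Ccl24, 0.18 for Jak3, Lrg1 and Igf2bp2, and 0.092 for Ffar2. Without GM-CSF replicate 2 it was 0.24 for Ccl24, Jak3, Lrg1 and Igf2bp2, and without GM-CSF replicate 3 it was 0.11 for Ccl24 and 0.155 for Lrg1, Ffar2 and Igf2bp2. Without GM-CSF with IL-10 replicate 1 or 3 Lrg1 had 0.095 and 0.085, without replicate 1 Ccl24 had 0.085 and Jak3 0.059, and without replicate 3 Ffar2 had 0.095 and Igf2bp2 0.206.

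Of the lists, the 25 alternative activation and tissue remodelling genes were higher with IL-10 on top of GM-CSF (mean 0.52, adjusted p = 5.08e-05, and 0.0091 with an estimated correlation), although edgeR called 0 members over all genes and 1 adjusted over the list alone, Mmp14 (2.39 ± 0.62). IL-10 and STAT3 targets had 1 of 19 called, Bcl3, and 5 adjusted over the list alone, and the list's adjusted p of 8.75e-09 was 0.19 with an estimated correlation. The 7 stromal and endothelial markers had a mean of 1.47 and 2 called adjusted over the list alone (adjusted p = 0.015, and 0.36 with an estimated correlation), and the fibroblast collagen Col1a1 stood at 4.82 CPM in GM-CSF with IL-10 replicate 3 and at 0.30 and 0.73 CPM in the other replicates of that group. Without that library the stromal list had an adjusted p of 0.685, without GM-CSF replicate 1 or 2 of 0.0746 and 0.0752, with limma-voom of 0.577 and without the 3 doubted libraries of 0.653. Mrc1, a member of the first list, was at 21.8, 62.6 and 8.44 CPM in the libraries with both cytokines.

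With IL-10 present, GM-CSF raised 86 genes and lowered 16 (57 and 12 by at least 2-fold). Ccl17 rose from 2.27 ± 0.49 to 86.5 ± 36.8 CPM (5.22 ± 0.44, adjusted p = 1.13e-06) and Ccl4 from 4.13 ± 1.24 to 48.9 ± 15.5 CPM (3.58 ± 0.27, adjusted p = 9.65e-08). Clec4n rose by 3.26 ± 0.30 and Il1b from 1.48 ± 0.24 to 13.3 ± 4.11 CPM (3.16 ± 0.36, adjusted p = 2e-05). Tnf (0.92 ± 0.12), Ccl3 (1.38 ± 0.15), Tlr2 (1.74 ± 0.19), Hbegf (1.76 ± 0.21) and the elastase gene Mmp12 (1.77 ± 0.27) rose as well. Plet1 had 1333 counts against 1, a ratio of 1195 (214 to 47219). Igf1 (-2.32 ± 0.34), Slc37a2 (-1.66 ± 0.29), the inositol-degrading enzyme Miox (-1.17 ± 0.20) and the G-CSF receptor gene Csf3r (-1.13 ± 0.21) fell. Of the 49 genes raised without IL-10, 44 were also raised with it, where independent lists would share 0.355. Of the 17 lowered ones 6 were (0.0229), and all 66 had the same sign. The count of 102 was 44 without IL-10 replicate 1 and 51 without IL-10 replicate 2.

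Chemokines (6 of 13 called, 8 adjusted over the list alone; adjusted p = 4.27e-37, and 0.00013 with an estimated correlation) were higher. So were STAT5 targets (4 of 18, including Cish and the feedback regulator genes Socs1 and Socs2; 9 higher and 1 lower adjusted over the list alone; 0.029 with an estimated correlation) and inflammatory cytokines (3 of 12; 6 higher and 1 lower adjusted over the list alone; 0.0016 with an estimated correlation). Without IL-10 replicate 1, Cish (0.59 ± 0.11) had an adjusted p of 0.056, Socs1 (1.21 ± 0.23) of 0.091 and Socs2 (0.66 ± 0.13) of 0.082, and without IL-10 replicate 2 Cish had 0.052. Without IL-10 replicate 3 or GM-CSF with IL-10 replicate 3, Socs2 had 0.094 and 0.11. Monocyte and macrophage markers were lower here too (median -0.71, 3 of 18 called and 4 adjusted over the list alone, camera adjusted p = 0.029 with an estimated correlation). The Y-linked sums were 186, 45.8 and 174 CPM with both cytokines and 59.9, 54.3 and 175 CPM with IL-10. In the same order the macrophage receptor gene Mrc1 was at 21.8, 62.6 and 8.44 CPM and at 91.9, 71.8 and 36.3 CPM. The comparison without IL-10 had a like imbalance of Y-linked sums, so it is not a separate check of this fall. Pattern-recognition and Fc receptors (4 of 24 called; 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0374, and 0.239 with an estimated correlation) and dendritic cell markers (2 of 15 called and 4 adjusted over the list alone, mean 0.43; adjusted p = 0.00936, and 0.252 with an estimated correlation) were higher with the preset correlation only. Without GM-CSF with IL-10 replicate 2 their adjusted p-values were 0.274 and 0.0863, without IL-10 replicate 3 they were 0.239 and 0.0526, and with limma-voom 0.558 and 0.122. The receptor list had 0.791 with no low-count filter. Of 14 lists called 8 held with an estimated correlation. The difference of the GM-CSF effect with and without IL-10 was tested directly, and edgeR called 0 genes (149 at an unadjusted p under 0.05; DESeq2 1; limma-voom 1). Il1b differed by 1.29 ± 0.49 and Ccl24 by -0.96 ± 0.59, both with an adjusted p of 1. Of 4 lists called for this difference 0 held with an estimated correlation, and the inflammatory cytokines came nearest (mean 0.33, adjusted p = 0.0016, and 0.055 with an estimated correlation; 0.0686 without GM-CSF replicate 3).

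The libraries labelled Csf2ra-/- asked whether the response needs the receptor chain. In them GM-CSF left Ccl17 at 2.74 ± 0.58 CPM against 3.94 ± 1.52 CPM untreated, Ccl4 at 3.37 ± 0.05 against 3.52 ± 0.45 CPM and Clec4n at 1.65 ± 0.88 against 1.56 ± 0.54 CPM (SD, n = 3). edgeR called 0 genes and 0 lists for GM-CSF in these cells (531 genes at an unadjusted p under 0.05; DESeq2 0; limma-voom 0), while the fit without untreated replicate 2 called 29. The model pairs no libraries, and replicate 3 stood apart in both groups, with the stress response gene Ddit3 (ENSMUSG00000025408) at 77.9 CPM untreated and 79.1 CPM with GM-CSF against 22.1 to 27.0 CPM in the other 4 libraries. With the score or the deviation on the leading axis of variation within groups as a covariate, settings chosen after seeing the data, edgeR called 0 genes again. Of the 66 genes called in wild type, 38 (57.6%) had the same sign here. Untreated Csf2ra-/- cells already had lower monocyte and macrophage markers than untreated wild type (median log2 fold change -2.01). A response lost within eosinophils and a lack of other responding cells therefore cannot be told apart here. The difference of the GM-CSF effect from wild type was tested directly. In Csf2ra-/- 6 genes had a lower log2 fold change than in wild type and 1 had a higher one. These were Ccl17 (-5.36 ± 0.64, adjusted p = 0.00089), Ccl4 (-2.87 ± 0.40, adjusted p = 0.00166), the carbonic anhydrase gene Car4 (-1.71 ± 0.24, adjusted p = 0.00166), Clec4n, Spp1 and the kinesin gene Kif1a on the one side and Egr1 on the other (1.84 ± 0.30, adjusted p = 0.0108). Egr1 fell with GM-CSF in wild type (-1.74 ± 0.22) and not in Csf2ra-/- (0.09 ± 0.21), so the difference came from the fall in wild type. The lack of a fall was not particular to Csf2ra-/-. GM-CSF left Egr1 at -0.08 ± 0.21 in the libraries labelled Irf5-/-. In wild type with IL-10 present Egr1 was at 138, 132 and 162 CPM with GM-CSF and at 160, 169 and 129 CPM without it. Kif1a was chosen after its values were seen, and had 2 counts with GM-CSF against 65 without in Csf2ra-/- (ratio 0.0292, 95% counting interval 0.0035 to 0.11), 54 of the 65 in replicate 3. In wild type it had 71 counts with GM-CSF and 9 without, so its change went in opposite directions in the 2 genotypes. Car4 stood at 262 ± 46.2 CPM with GM-CSF and 92.3 ± 15.5 CPM without it in wild type and at 80.8 ± 10.1 and 93.3 ± 13.0 CPM in Csf2ra-/-. Of the 38 genes raised at least 2-fold in wild type 5 had a smaller rise, against 0.0192 for independent lists. In 10 simulated runs with no effect there were at most 0. Those runs held no gene that GM-CSF truly raised, so they do not measure what the choice of raised genes adds to the 5. The choice of the 38 and the difference share the 6 wild-type libraries, so part of the excess may come from them. At an unadjusted p under 0.05 stood 692 genes, DESeq2 called 27 genes and limma-voom 2.

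The chemokine list responded less in Csf2ra-/- (2 of 13 called, 6 adjusted over the list alone, mean -1.36; adjusted p = 1.74e-19, and 0.0033 with an estimated correlation). So did costimulatory and checkpoint ligands (0 called over all genes and 3 adjusted over the list alone, Tnfsf4 at -2.62 ± 0.52; adjusted p = 0.00233, and 0.032 with an estimated correlation). Apoptosis regulators did too (0 and 3, with Bcl2a1d at -2.39 ± 0.56; adjusted p = 0.00167, and 0.046 with an estimated correlation). Of 10 lists called these 3 held with an estimated correlation. The count of 7 was 4 without untreated Csf2ra-/- replicate 1, untreated wild-type replicate 2 or untreated wild-type replicate 3, and 12 without untreated Csf2ra-/- replicate 2. The ligand list had an adjusted p of 0.055 without untreated Csf2ra-/- replicate 2 and of 0.0525 with limma-voom. Ccl17, Ccl4 and Car4 kept their calls whichever library was left out. Egr1 lost it without untreated Csf2ra-/- replicate 1 (adjusted p = 0.092), GM-CSF Csf2ra-/- replicate 3 (0.051) or untreated wild-type replicate 2 (0.055) or 3 (0.065). Spp1 (-1.49 ± 0.27, adjusted p = 0.03) lost it in 9 of the 12 fits (adjusted p up to 0.16), all but those without untreated Csf2ra-/- replicate 2 or wild-type untreated replicate 1 or GM-CSF replicate 3. Clec4n (-2.82 ± 0.50) lost it without untreated Csf2ra-/- replicate 1 (0.095) or 3 (0.26), GM-CSF Csf2ra-/- replicate 1 (0.081) or 2 (0.068), untreated wild-type replicate 2 (0.092) or 3 (0.071), or wild-type GM-CSF replicate 1 (0.081).

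**Figure D3:**
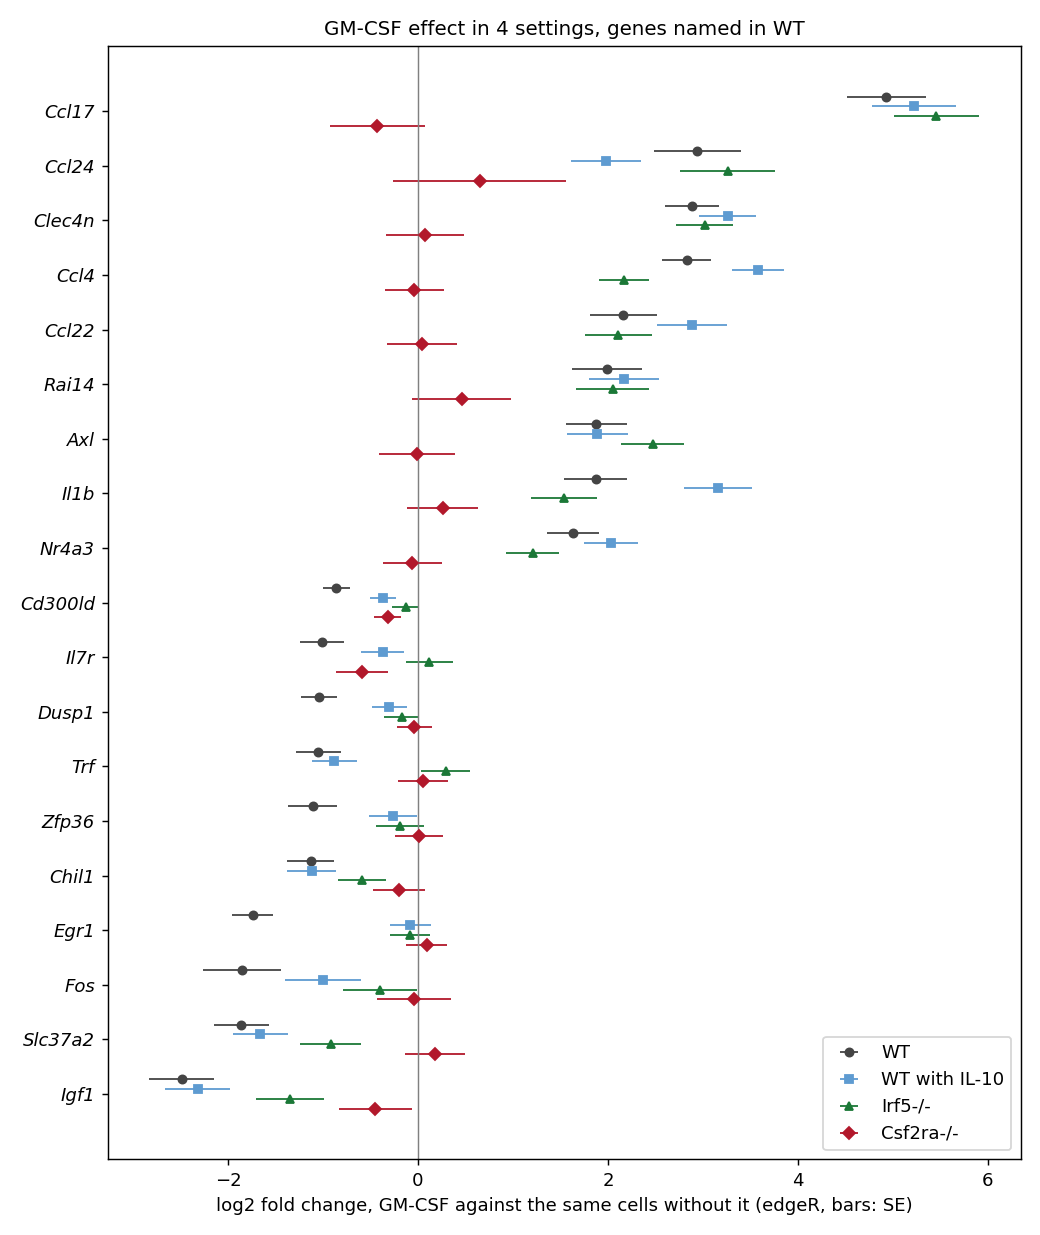
Log2 fold change with GM-CSF (horizontal axis, edgeR, bars are SE) of the genes named for the wild-type effect, except Plet1, in wild type, in wild type with IL-10, in the libraries labelled Irf5-/- and in those labelled Csf2ra-/-, each from 3 against 3 libraries. Ccl17 lies at 4.93, 5.22, 5.46 and -0.43 in that order and Egr1 at -1.74 in wild type and -0.08 in the libraries labelled Irf5-/-.

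In the libraries labelled Irf5-/-, whose Irf5 count was high, GM-CSF raised 42 genes and lowered 0 by edgeR. At an unadjusted p under 0.05 stood 692 genes, and DESeq2 called 78 genes and limma-voom 58. The model paired no libraries, and no paired fit was run. By replicate number the Y-linked sums were 179, 12.2 and 39.2 CPM untreated and 165, 13.4 and 44.2 CPM with GM-CSF. Ccl17 rose from 2.80 ± 0.29 to 122 ± 62.2 CPM (SD, n = 3; 5.46 ± 0.45, adjusted p = 1.68e-06) and Clec4n from 4.05 ± 1.02 to 33.8 ± 7.74 CPM (3.02 ± 0.30, adjusted p = 7.06e-06). Ccl24 rose from 1.02 ± 0.60 to 10.8 ± 7.03 CPM (3.26 ± 0.50, adjusted p = 0.00253) and Ccl4 from 7.33 ± 1.79 to 32.9 ± 6.59 CPM (2.17 ± 0.26, adjusted p = 7.33e-05). Tlr2 (1.52 ± 0.20) and Ccnd2 (0.68 ± 0.11) rose too, and Plet1 had 1392 counts against 2, a ratio of 633 (175 to 5233). Il1b stood at 1.54 ± 0.35 (adjusted p = 0.0548), Igf1 at -1.35 ± 0.36 (adjusted p = 0.168) and Egr1 at -0.08 ± 0.21. Of the 49 genes raised in wild type 27 were also raised here, where independent lists would share 0.173, and 63 of the 66 called genes (95.5%) had the same sign. Chemokines were higher as a list (5 of 13 called, 8 adjusted over the list alone; adjusted p = 4.35e-28, and 0.00062 with an estimated correlation). Alternative activation and tissue remodelling genes were higher (3 of 25 called; 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00196, and 0.035 with an estimated correlation), with an adjusted p of 0.114 without untreated replicate 1 and 0.112 without the 3 doubted libraries. MHC class II genes had a median of 1.07 and a mean of 0.83 (0.40 without GM-CSF replicate 1), 0 of 11 called over all genes and 7 adjusted over the list alone, and an adjusted p of 4.46e-08 that was 0.15 with an estimated correlation. Dendritic cell markers had a median of 0.45 and a mean of 0.77 (0.49 without GM-CSF replicate 1), 1 of 15 called over all genes and 3 adjusted over the list alone, and an adjusted p of 2.26e-05 that was 0.0847 with an estimated correlation. GM-CSF replicate 1 stood apart from replicates 2 and 3, with Ddit3 (ENSMUSG00000025408) at 72.1 CPM against 34.0 and 27.9 CPM and Mrc1 at 12.7 CPM against 5.16 and 2.83 CPM.

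The difference of the GM-CSF effect between the libraries labelled Irf5-/- and wild type was tested directly, and edgeR called 0 genes (375 at an unadjusted p under 0.05; DESeq2 1; limma-voom 1). Ccl17 differed by 0.52 ± 0.60, Ccl4 by -0.65 ± 0.36 and Clec4n by 0.13 ± 0.40, and Egr1 by 1.67 ± 0.30 (adjusted p = 0.194). Of 11 lists called for this difference 0 held with an estimated correlation. For GM-CSF in the libraries labelled Irf5-/- themselves 12 lists were called and 2 held. The count of 42 was 16 without untreated replicate 1, 16 without untreated replicate 2, 21 without untreated replicate 3 and 11 without GM-CSF replicate 1. With covariates chosen after seeing the data it was 40 with the Y-linked level, 95 with the axis score and 173 with the axis deviation. The axis covariates take up part of the spread within groups, so their higher counts do not strengthen the result.

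In the main fit 656 genes were called higher and 632 lower in untreated Csf2ra-/- than in untreated wild-type cells (57 and 280 by at least 2-fold). The count depended on the fit, as given below. The lower genes included many of monocytes and macrophages. The chemokine receptor gene Ccr2 went from 26.0 ± 1.71 CPM in wild type to 6.06 ± 1.15 CPM (SD, n = 3; -2.12 ± 0.28, adjusted p = 0.000121). The pore-forming protein gene Mpeg1 went from 54.4 ± 7.96 to 19.7 ± 4.80 CPM (-1.48 ± 0.21, adjusted p = 0.000228). The lysozyme gene Lyz2 went from 234 ± 50.5 to 109 ± 17.8 CPM (-1.11 ± 0.18, adjusted p = 0.000765), and Emp1, a membrane protein gene, from 12.6 ± 1.28 to 2.31 ± 0.47 CPM (-2.43 ± 0.35, adjusted p = 0.000265). Of 18 monocyte and macrophage markers 13 were lower and 1 higher (16 and 2 adjusted over the list alone), with a median of -2.01 (adjusted p = 6.3e-13, and 0.0094 with an estimated correlation). Pattern-recognition and Fc receptors followed (11 of 24 lower; 12 lower and 1 higher adjusted over the list alone; 0.005 with an estimated correlation), with the scavenger receptor gene Cd36 at -2.15 ± 0.29 and the lectin gene Clec4d at -1.52 ± 0.20. Alternative activation and tissue remodelling genes (11 of 25 lower under both adjustments, such as Chil3 at -1.79 ± 0.28 and Mmp12 at -1.68 ± 0.27; 0.0016 with an estimated correlation) were also lower. Cytokine receptors and signal transducers (8 of 31 lower, 11 adjusted over the list alone, with Il6ra at -1.91 ± 0.27 and Csf3r at -1.30 ± 0.21; 0.005 with an estimated correlation) were lower as well.

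Of 19 lists called the 4 above held with an estimated correlation. On the other side, 22 of 30 cell cycle and DNA replication genes were higher in Csf2ra-/- (29 adjusted over the list alone), among them the mitotic activator gene Cdc20 at 78.7 ± 17.1 against 46.2 ± 7.74 CPM (0.76 ± 0.15) and the replicative helicase gene Mcm7 at 147 ± 17.1 against 97.0 ± 14.4 CPM (0.60 ± 0.12). The list's adjusted p of 1.39e-17 was 0.13 with an estimated correlation. Ribosome biogenesis genes were 8 of 24 higher (13 adjusted over the list alone, Nop56 at 0.77 ± 0.15), with an adjusted p of 0.15 with an estimated correlation. MHC class II genes were 6 of 11 lower under both adjustments (Ctss at -1.68 ± 0.35 and Cd74 at -1.77 ± 0.38; 0.15 with an estimated correlation), and chemokines 7 of 13 lower (10 lower and 1 higher adjusted over the list alone, Ccl9 at -1.26 ± 0.24; 0.077 with an estimated correlation). Dendritic cell markers were 4 of 15 lower (6 adjusted over the list alone, median -0.92, mean -0.96; adjusted p = 0.0023, and 0.148 with an estimated correlation; 0.053 without untreated Csf2ra-/- replicate 2 and 0.054 with limma-voom). The largest rises were the beta globin gene Hbb-bt (1.84 ± 0.23, adjusted p = 7.64e-05) and the carboxylesterase gene Ces2g (1.72 ± 0.24, adjusted p = 0.000186). Of 25 eosinophil granule and lineage genes 3 were higher and 3 lower (9 and 6 adjusted over the list alone), with the lipoxygenase gene Alox15 at -0.61 ± 0.12, Prg2 at 0.24 ± 0.12 and Siglecf at 0.16 ± 0.18, and Csf2rb at -0.38 ± 0.13 (adjusted p = 0.0737). The count of 1288 was 359 without untreated Csf2ra-/- replicate 1, 2620 without replicate 2, 291 without untreated wild-type replicate 2 and 520 without wild-type replicate 3, and it was 388 without the 3 doubted libraries together. With only the groups compared in the fit it fell below all of these, as given in the part on processing. The main model fits 1 spread per gene for all groups, while the untreated Csf2ra-/- libraries differed more among themselves than the untreated wild-type ones. The chi-square per degree of freedom between pairs of replicates was 34.85 to 66.26 against 7.08 to 16.3. limma-voom called 309, all among the 1288. The stress response gene Ddit3 (ENSMUSG00000025408) was at 27.0, 22.1 and 77.9 CPM in these Csf2ra-/- libraries and 57.8, 81.9 and 88.6 CPM in wild type. With the axis score as a covariate 2236 genes were called. That rise is no check of the count, since the score takes up part of the spread within groups. The Y-linked sum was 162 to 181 CPM in the Csf2ra-/- libraries and 175, 56.9 and 50.7 CPM in wild type, and with it as a covariate 747 genes were called, 731 of them among the 1288.

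**Figure D4:**
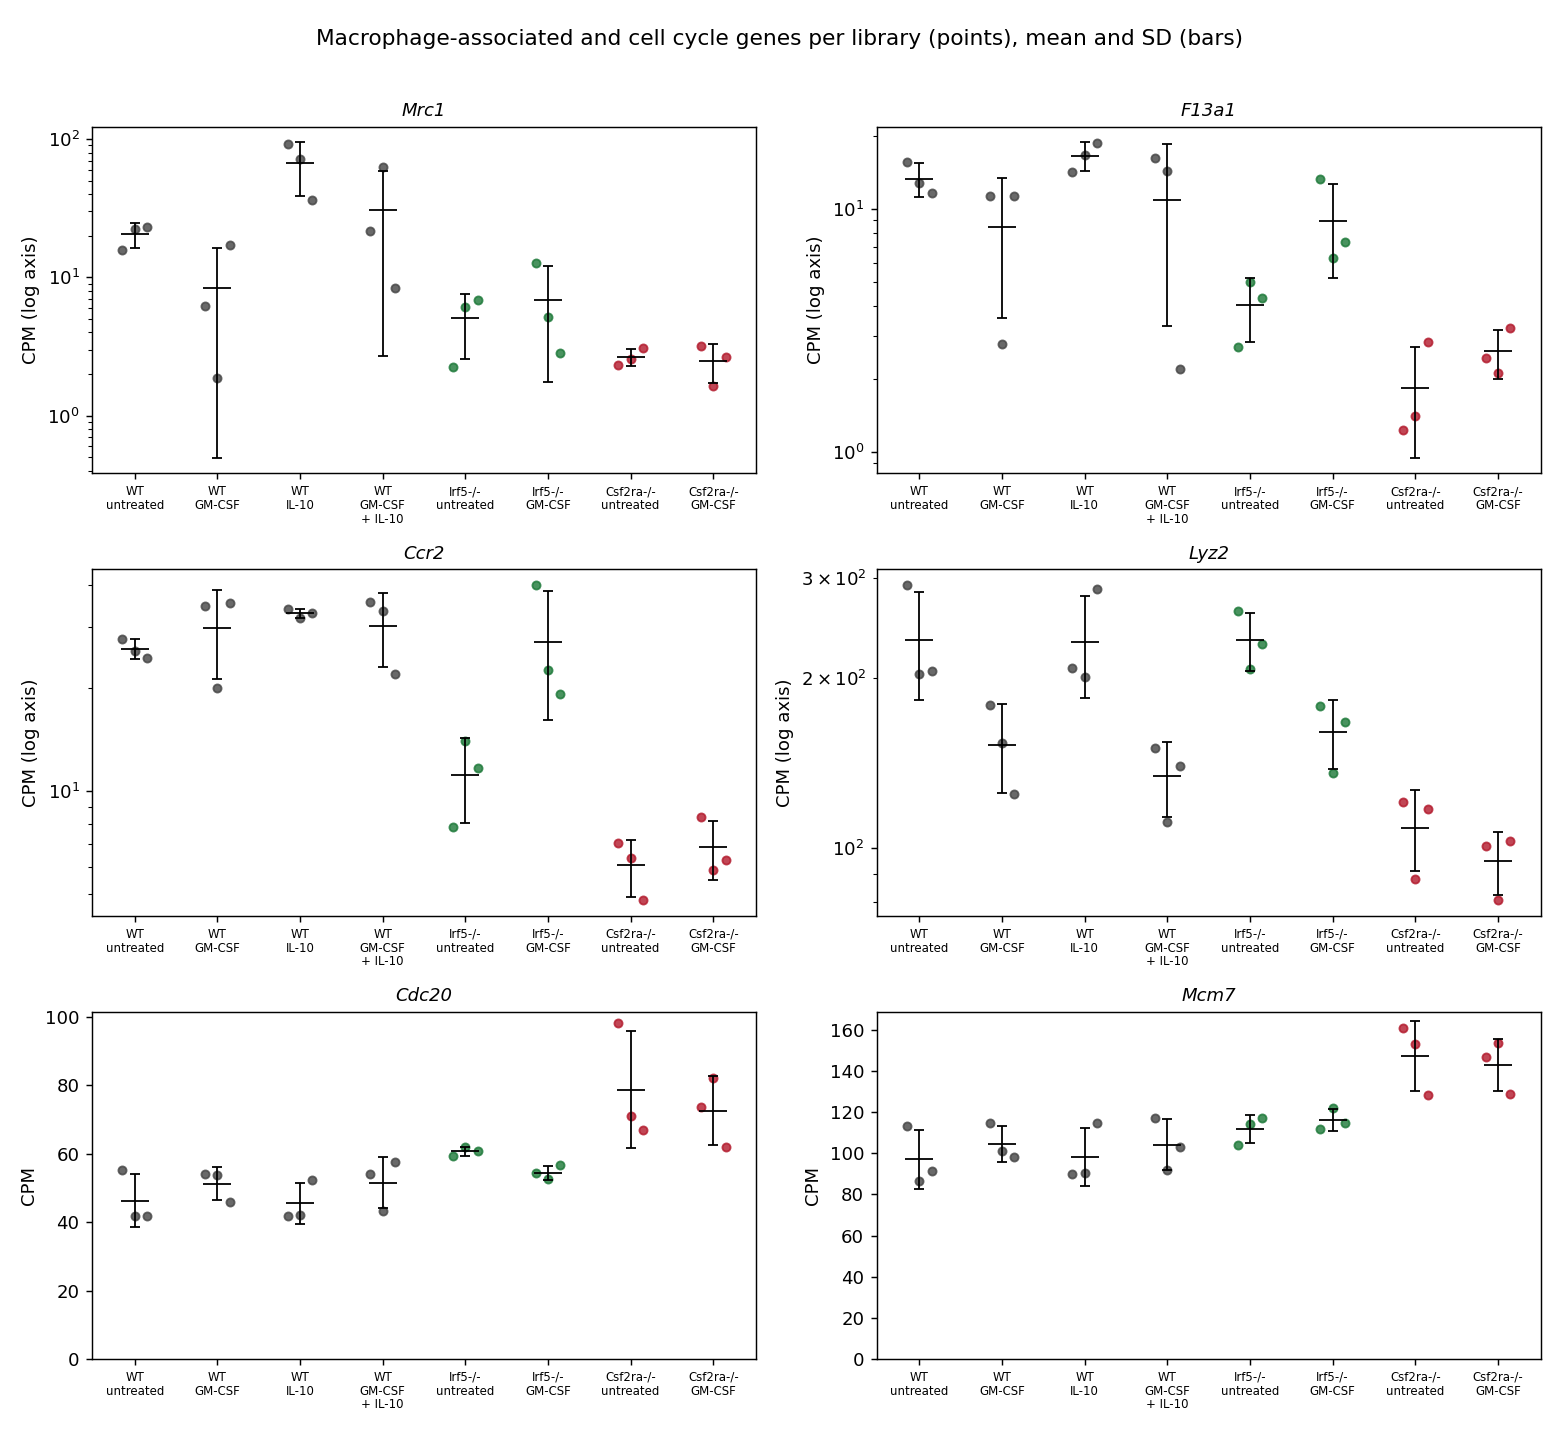
TMM-scaled CPM of the macrophage-associated genes Mrc1, F13a1, Ccr2 and Lyz2 (log axes) and of the cell cycle genes Cdc20 and Mcm7 (linear axes) in the 8 groups, with 1 point per library and the mean and SD of 3 libraries as bars. Ccr2 is at 26.0 CPM in untreated wild type and 6.06 CPM in untreated Csf2ra-/-, and Cdc20 at 46.2 and 78.7 CPM.

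In the main fit few genes were called between the libraries labelled Irf5-/- and wild type. For the untreated cells that count depended on the fit, so it does not show that few genes differ. limma-voom called 581 there, and the fit of only the groups compared rose to a like number, given in the part on processing. Untreated, 4 genes passed, with Irf5 itself highest (4.95 ± 0.19, adjusted p = 4.44e-14). It was followed by the stress kinase gene Plk3 at 34.4 ± 2.89 against 16.4 ± 0.48 CPM (1.07 ± 0.18, adjusted p = 0.0192). The methyltransferase gene Bmt2 (32.7 ± 4.79 against 56.5 ± 5.03 CPM; -0.78 ± 0.14, adjusted p = 0.0276) and the small GTPase gene Rab7b (-1.61 ± 0.25, adjusted p = 0.0105) were lower. Rab7b lay outside the rule for named genes and was chosen after its values were seen, at 1.93 ± 0.63 against 6.18 ± 0.59 CPM. It lost its call without untreated replicate 1 of the libraries labelled Irf5-/- (adjusted p = 0.0904) or wild-type replicate 2 (0.0968) or 3 (0.0572). At an unadjusted p under 0.05 stood 1668 genes, DESeq2 called 23 genes and limma-voom 581. Plk3 lost its call without untreated replicate 1 (adjusted p = 0.09) or 2 (0.22) of the libraries labelled Irf5-/- or without wild-type replicate 1 (0.086), 2 (0.15) or 3 (0.1), and Bmt2 in the same 5 fits (0.21, 0.44, 0.067, 0.35 and 0.1). The count of 4 was 1 without untreated replicate 1 of the libraries labelled Irf5-/- or without wild-type replicate 2 or 3, 2 without replicate 2 of the former or replicate 1 of wild type, and 8 without replicate 3 of the former. Of 15 lists called, among them monocyte and macrophage markers with a median of -0.67, 0 held with an estimated correlation (adjusted p of 0.32 or higher). The stress response gene Ddit3 (ENSMUSG00000025408) was at 25.0, 36.6 and 28.9 CPM in these libraries and 57.8, 81.9 and 88.6 CPM in untreated wild type. With the axis deviation as a covariate 1287 genes were called. That rise is no evidence for more changed genes, since the deviation takes up part of the spread within groups. With GM-CSF, 4 genes were higher. They were Irf5 (4.44 ± 0.18, adjusted p = 2.49e-13) and Egr1 at 451 ± 46.2 against 98.2 ± 27.1 CPM (2.20 ± 0.22, adjusted p = 1.07e-05). The others were the phosphatase gene Dusp1 at 81.0 ± 11.9 against 34.4 ± 8.76 CPM (1.23 ± 0.19, adjusted p = 0.00526) and the early activation marker Cd69 at 38.6 ± 8.72 against 19.5 ± 3.05 CPM (0.98 ± 0.18, adjusted p = 0.0392). Csf2ra-/- libraries with GM-CSF had Egr1 at 370, 391 and 493 CPM and Dusp1 at 74.6, 78.9 and 79.4 CPM. For Egr1 and Dusp1 the higher level was thus not particular to the libraries labelled Irf5-/-. At an unadjusted p under 0.05 stood 173 genes, DESeq2 called 8 and limma-voom 11. The count of 4 was 2 without replicate 2 of the libraries labelled Irf5-/- with GM-CSF or without wild-type GM-CSF replicate 1 or 3. Egr1 kept its call whichever library was left out, and Dusp1 lost it without replicate 2 of the libraries labelled Irf5-/- with GM-CSF (adjusted p = 0.09) or wild-type GM-CSF replicate 1 (0.12) or 3 (0.075). Cd69 lost it in those fits (0.63, 0.31 and 0.37) and without replicate 3 of the libraries labelled Irf5-/- with GM-CSF (0.24) or wild-type GM-CSF replicate 2 (0.062). The 9 interferon regulatory factor genes were higher as a list (adjusted p = 5.37e-12, and 0.009 with an estimated correlation), a call carried by Irf5, since the median was -0.02 and the mean 0.41, and 1 member passed under both adjustments. Its adjusted p was 0.292 with limma-voom and 0.275 with no low-count filter.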

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

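All tests in this part were chosen after the results were seen, except the direct test of the difference in GM-CSF effects between Csf2ra-/- and wild type. A direct test of that difference called 7 genes, which is what brought it here. Ccl17 (-5.36 ± 0.64), Ccl4 (-2.87 ± 0.40), Clec4n (-2.82 ± 0.50), Car4 (-1.71 ± 0.24) and Spp1 (-1.49 ± 0.27) responded less in Csf2ra-/-. Egr1 differed by 1.84 ± 0.30, since it fell in wild type (-1.74 ± 0.22) and not in Csf2ra-/- (0.09 ± 0.21). In the libraries labelled Irf5-/- it did not fall with GM-CSF either (-0.08 ± 0.21). Kif1a was fitted at -7.43 ± 1.18, a value that depends on the prior count. It had 2 counts over the 3 GM-CSF libraries and 65 over the 3 untreated libraries of Csf2ra-/-, 54 of them in replicate 3, a ratio of 0.0292 with a 95% counting interval of 0.0035 to 0.11. In wild type it had 71 counts with GM-CSF and 9 without. It was chosen after its values were seen. The lists of chemokines (mean -1.36), costimulatory and checkpoint ligands (mean -0.53, with an adjusted p of 0.0525 by limma-voom) and apoptosis regulators (mean -0.28) also responded less. Of the 12 fits that leave out 1 library, Ccl17, Ccl4, Car4 and Kif1a passed in all, Egr1 in 8 (adjusted p up to 0.092 in the others) and Clec4n in 5 (up to 0.26). Spp1 passed only without untreated Csf2ra-/- replicate 2, GM-CSF wild-type replicate 3 or untreated wild-type replicate 1 (adjusted p up to 0.16 in the others).

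Regrouping the libraries bears on whether chance can be excluded for each count. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. The real split gave 66 genes for GM-CSF in wild type, 6 for IL-10 alone, 6 for IL-10 with GM-CSF, 102 for GM-CSF with IL-10, 42 for GM-CSF in the libraries labelled Irf5-/-, and 4 and 4 for those libraries against wild type without and with GM-CSF. The highest other split gave 0 in each of these, and only the real split, 1 of 10, gave as many. For untreated Csf2ra-/- against wild type the real split gave 1288 and the highest other 948. For GM-CSF in Csf2ra-/- the real count of 0 fixes that all 10 splits gave as many, and the split that put untreated replicates 1 and 3 with GM-CSF replicate 3 gave 3126, which points to a structure among these 6 libraries other than treatment. For the difference in GM-CSF effects between Csf2ra-/- and wild type, 12 of 100 splits, the real one included, gave 7 genes or more. These splits move libraries between genotypes with 1288 genes called between them untreated, so they do not measure chance for that count. The highest, 1705, had 1 Csf2ra-/- and 2 wild-type libraries in its first set both untreated and with GM-CSF, and points again to a structure of the samples. For the differences with and without IL-10 and between the libraries labelled Irf5-/- and wild type the real count of 0 fixes that all 100 splits gave as many. The highest gave 41 and 498, and neither measures chance, since the first is the IL-10 effect summed over cells with and without GM-CSF and the second moves libraries between genotypes.

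The first pattern weighed is the high Irf5 count in the libraries labelled Irf5-/-. Single libraries swapped between groups would put at least 1 of the 6 among the other 18, and the lowest of the 6 lay 14.8 times above the highest of the 18; labels exchanged between whole groups would make the high level that of an intact gene, yet any exchange leaves at least 4 groups with an intact gene among the other 6, and the highest mean of those 6 lay 21.7 times below the lower mean of the 2. Transcription raised across the whole region would lift the neighbours, and the 11 tested genes within 0.5 Mb had a median of -0.12 (SD 0.76) with 0 called by edgeR; this test first used the highest neighbour, 1.21, and was changed to the median after that value was seen. A transcript of the targeted allele counted whole may explain the log2 fold change of 4.95, and it stays open because counts per gene do not separate exons; a vector or strain that expresses Irf5 was not tested.

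The second pattern weighed is the lower level of some immediate early genes in wild type with GM-CSF. Handling before lysis that acts on these genes together and equally would move them all by about the change of Egr1. The 21 listed genes had a median of -0.30 (SD 0.82), with 15 below 0. Of the 21, 4 were called lower (Egr1, Fos, Zfp36 and Dusp1) and 1, Nr4a3, higher. Handling that moves the genes by unequal amounts could give such a median, so this test does not decide about handling. With the score on the main axis of variation within groups as a covariate Egr1 stood at -1.70 ± 0.22, and with the Y-linked level at -1.71 ± 0.22, against -1.74 ± 0.22 without, so these 2 trends do not carry its change. A handling effect of unequal size across the genes and an effect of GM-CSF stay open. A candidate explanation must also meet the values in IL-10 alone and in both cytokines. There Egr1 was at 153 ± 20.8 and 144 ± 15.9 CPM. It must meet as well that Egr1 did not fall with GM-CSF in the libraries labelled Irf5-/- (log2 fold change -0.08 ± 0.21).

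The third pattern weighed is the 1288 genes that the main fit called between untreated Csf2ra-/- and wild type, a count that depended on the fit. A mix of male and female cells would take away most of the change once the Y-linked level is a covariate, and the genes kept a median of 96.8% of it (MAD 6.36), all 1288 with the same sign; this test was first the percent still called, 56.8%, and was changed after that value was seen. Fewer macrophage-like cells in Csf2ra-/- may explain genes that are lower, since the macrophage markers had a median of -2.01 over 18 genes listed before the data were examined; for the 656 genes that are higher it was not tested. Variants carried with the targeted region may explain the genes near Csf2ra, of which 6 of 13 within 3 Mb were called, all lower, against 10.8% elsewhere (Fisher exact p = 0.0014). Whether receptor loss acts within eosinophils or through the cells that accompany them was not tested.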

How the results depend on the processing

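The covariates (Y-linked level, score and deviation on the main axis of variation within groups) and the fit without the 3 doubted libraries were chosen after the results were seen, and all other settings before. Where a value below moved, the cause was not tested. Of 220 named gene results that passed, 217 passed with RLE scaling, 220 with DESeq2, 219 with a stricter low-count filter, 201 with no filter and 153 with limma-voom. There were 188 with the Y-linked level and 151 without the 3 doubted libraries. With the axis score there were 217 and with the axis deviation 220. All calls kept were in the same direction. The axis counts here and below do not measure robustness, since both covariates come from the libraries' own spread within groups. With only the groups compared in the fit 126 passed and 92 did not, and with 1 library left out 931 fits passed and 425 did not. Of 118 gene list results that passed, 25 did so with an estimated correlation.

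By DESeq2 the counts were 112 for GM-CSF in wild type (main value 66), 30 for IL-10 alone (6), 21 for IL-10 with GM-CSF (6), 168 for GM-CSF with IL-10 (102). It also gave 1 for the difference with and without IL-10 (0), 78 for GM-CSF in the libraries labelled Irf5-/- (42), 1 for the difference of these from wild type (0), 27 for the difference of Csf2ra-/- from wild type (7), and 23 and 8 for the libraries labelled Irf5-/- against wild type untreated and with GM-CSF (4 and 4). In that order limma-voom gave 216, 138, 19, 1317 and 1, then 1 for the difference of the libraries labelled Irf5-/-, 2 for the Csf2ra-/- difference, 581 and 11, and it gave 309 for untreated Csf2ra-/- against wild type (1288). With the axis score as covariate the counts were 152 for GM-CSF in wild type, 44 and 33 for IL-10 without and with GM-CSF, 270 for GM-CSF with IL-10, 95 for GM-CSF in the libraries labelled Irf5-/-, 23 for the Csf2ra-/- difference, 2236 for untreated Csf2ra-/- and 11 for the libraries labelled Irf5-/- with GM-CSF. With the axis deviation they were 219, 44, 33, 358, 173, 22, 3005 and 12 in that order, and 23 for the difference of the libraries labelled Irf5-/- and 1287 for the untreated libraries labelled Irf5-/-. With the Y-linked level, IL-10 with GM-CSF gave 3 and untreated Csf2ra-/- 747. Without the 3 doubted libraries, GM-CSF in the libraries labelled Irf5-/- gave 19, the Csf2ra-/- difference 4, untreated Csf2ra-/- 388 and the untreated libraries labelled Irf5-/- 2. With only the groups compared, IL-10 alone gave 44, IL-10 with GM-CSF 0, the Csf2ra-/- difference 3, untreated Csf2ra-/- 199, and the libraries labelled Irf5-/- 562 untreated and 2 with GM-CSF. With no low-count filter the untreated libraries labelled Irf5-/- gave 9.

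Among shared genes, those with a smaller rise in Csf2ra-/- (5) were 19 by DESeq2, 2 by limma-voom, 10 with either axis covariate, and 3 without the 3 doubted libraries or with only the groups compared. Genes raised by GM-CSF in both wild type and the libraries labelled Irf5-/- (27) were 48 by DESeq2, 44 by limma-voom, 60 and 65 with the axis score and deviation, and 16 without the doubted libraries or with only the groups compared. Those lowered in both (0) were 1, 2, 5, 5 and, with only the groups compared, 1. Genes raised by GM-CSF without and with IL-10 (44) were 69, 134, 89, 101 and, with only the groups compared, 26, and those lowered (6) were 14, 42, 24 and 39. Genes raised by IL-10 in both comparisons (2) were 12, 18, 21 and 22, 1 with no filter or with the Y-linked level, and 0 with only the groups compared.

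Leaving out 1 library, the counts ranged from 31 to 61 for GM-CSF in wild type, 0 to 7 for IL-10 alone, 0 to 6 for IL-10 with GM-CSF, 44 to 100 for GM-CSF with IL-10 and 0 to 0 for the difference with and without IL-10. They ranged from 0 to 29 for GM-CSF in Csf2ra-/-, 4 to 12 for the Csf2ra-/- difference, 11 to 41 for GM-CSF in the libraries labelled Irf5-/-, 0 to 0 for the difference of the libraries labelled Irf5-/-. They ranged from 291 to 2620 for untreated Csf2ra-/-, and 1 to 8 and 2 to 5 for the libraries labelled Irf5-/- untreated and with GM-CSF. A group left with 2 libraries was assumed to vary like the others. For the untreated libraries labelled Irf5-/- the axis score turned the mean of STAT5 targets from -0.06 to 0.10 and of IL-10 and STAT3 targets from -0.19 to 0.0044. For IL-10 with GM-CSF, the mean of cell cycle genes went from -0.0068 to 0.0918 without GM-CSF with IL-10 replicate 2 (range -0.0773 to 0.0918 over the libraries left out), and that of MHC class II genes from 0.03 to -0.2155 without GM-CSF replicate 2 (range -0.2155 to 0.2758).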

Other observations

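The values in this part were looked at after the results were seen, and no explanation was tested for them. The leading axis of the deviations from the group means held 29.5% of the variance within groups, against 12.9% for the next. The stress response genes Ddit3 and Trib3 ranged from 22.1 to 110 CPM (ENSMUSG00000025408) and from 18 to 92.4 CPM over the 24 libraries. In untreated cells Ddit3 was at 57.8, 81.9 and 88.6 CPM in wild type, 27.0, 22.1 and 77.9 CPM in Csf2ra-/- and 25.0, 36.6 and 28.9 CPM in the libraries labelled Irf5-/-, and Trib3 at 50.7, 76.1 and 79.8, at 24.8, 19.4 and 57.7, and at 22.2, 25.0 and 23.9 CPM. The sum of 4 Y-linked genes was 152 to 184 CPM in the 6 libraries labelled Csf2ra-/-. In the libraries labelled Irf5-/- it was 179, 12.2 and 39.2 CPM untreated and 165, 13.4 and 44.2 CPM with GM-CSF, and in wild type with IL-10 it was 59.9, 54.3 and 175 CPM, and with both cytokines 186, 45.8 and 174 CPM. The fibroblast collagen Col1a1 was at 14.98 and 13.97 CPM in replicate 2 of the libraries labelled Irf5-/- without and with GM-CSF. Mrc1 was at 91.9, 71.8 and 36.3 CPM in the wild-type libraries with IL-10 and at 15.7, 22.6 and 23.1 CPM in the untreated ones (log2 fold change 1.71 ± 0.65, adjusted p = 0.907).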
